A study of Mus musculus with 6 samples.

How the data were processed

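Single-cell 3' messenger RNA libraries (10x Genomics v3.1 chemistry, per the labels' protocols) were examined from sorted CD3+CD8+ T cells of C57BL/6J mice infected with Toxoplasma gondii. Per the labels' protocols, brain tissue was digested with DNase and collagenase/dispase and separated on 30% Percoll, whereas spleen was pressed through a strainer and red cells were lysed. Reads were processed with Cell Ranger 5.0.1 on mm10, per the submitters' processing notes. The annotation release and the handling of intronic reads are not given in the sources used here. The deposited values are raw UMI counts for all barcodes and 32285 genes, unfiltered and not normalized, and all columns of the matrices were read. Of the gene IDs, 32158 were matched in GENCODE vM21, which gave the positions.

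The 6 libraries were grouped by title. The other labels of the spleen libraries call them brain, and the group was taken from the title. Brain mGluR-positive replicates 1 and 3 shared 293 of their 300 richest barcodes, and 74.08% of 288132 gene entries of their 127 shared cells were equal. Libraries that shared at least 150 of these barcodes were merged, so both entered every test as 1 library with the rounded mean of their counts. The design had assumed 3 distinct replicates. It remains unknown which of both files is the intended one.

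Barcodes were called cells when they held at least 0.1 times the 99th percentile of the 3000 richest barcodes. This gave 6722 called cells for brain mGluR-negative, 182, 283 and 179 for brain mGluR-positive replicates 1 to 3, 15695 for spleen mGluR-negative and 3844 for spleen mGluR-positive. A limit of at least 500 UMIs would have called 7688, 452, 2081, 444, 16635 and 44942 barcodes in the same order. Cells with fewer than 200 genes or over 10% mitochondrial UMIs were left out, as were the highest Scrublet scores at a rate of 0.8% per 1000 cells. The kept cells were normalized, reduced to 2000 variable genes and 30 principal components, joined by 15 nearest neighbours and clustered with the Leiden method at resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, seed 1), which gave 27 clusters. Clusters were named by marker lists of T cell classes, NK cells, B cells, plasma cells, monocytes or macrophages, microglia, dendritic cells, neutrophils, mast cells or basophils, erythroid cells, platelets or megakaryocytes, endothelial cells, neurons, astrocytes, oligodendrocytes and choroid plexus or ependyma. A T-like cluster needed at least 3 of the 7 CD8 T cell markers, each detected in at least 0.5 of its cells, and no other class with more markers than T cells among its 10 leading genes against clusters that lacked those markers. T-like cells had median depths of 3891, 5868, 6189, 5836, 9062 and 7232 UMIs in the library order above. Free RNA was measured in barcodes of 1 to 50 UMIs.

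UMIs were summed over the T-like cells of each library. Brain mGluR-positive cells were compared with brain mGluR-negative cells and with spleen mGluR-positive cells by edgeR 4.0.16 (filterByExpr, TMM factors, estimateDisp, glmQLFit and glmQLFTest, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05 over all genes tested. Standard errors are the absolute log2 fold change divided by the square root of F. With 2 libraries against 1 the fit had 1 residual degree of freedom, and edgeR shared the spread fully across genes. A gene whose 2 positive libraries differ widely can therefore pass. Gene lists were tested with camera of limma 3.58.1 with the correlation preset at 0.01, and again with the correlation estimated and with fry. The latter 2 rest on the 1 residual degree of freedom and have almost no power here. A list that fails them is thereby neither upheld nor refuted. The 18 lists were glutamate receptors, glutamate transport and metabolism, Gq and calcium signalling, cytotoxic effector, naive and central memory, memory CD8, resident memory, exhaustion, proliferation, interferon response, immediate early and dissociation stress, TCR activation, glycolysis, oxidative phosphorylation, chemokine receptors and homing, apoptosis, ribosomal protein and class II antigen presentation genes. The difference between the brain change and the spleen change was tested in 1 edgeR fit of all groups, whose spread comes from the brain mGluR-positive libraries.

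Comparisons of 1 library with 1 have no test. They give the log2 ratio of CPM + 1 for genes with at least 100 UMIs, exact Poisson intervals at 95%, and the percentile of each list's median among 10000 random lists matched on mean expression in 20 bins. Genes of the random lists were drawn singly, here and in the tested comparisons. Such a percentile ignores list members that vary together and spread between libraries, and is no p-value. Where a group had 0 UMIs, fold changes are bounded by a floor of 3 counts per library, the largest in the group. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, and groups were compared by an exact permutation of libraries. Markers of neurons, astrocytes, oligodendrocytes, choroid plexus or ependyma and microglia were used for free RNA. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

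Gene names were chosen by a rule set before the data were examined, as were the gene lists, the tests and most alternatives. The rule names the 10 largest changes per direction that passed, went the same way in all positive libraries and reached 20 CPM, then 22 fixed genes, and up to 4 members per list with the smallest adjusted p. Some genes that the rule names are not reported here. Immunoglobulin genes, T cell receptor segments, mitochondrial and ribosomal protein genes and unnamed gene models were summarised apart from it. Several choices were made after the data were seen: the merging of replicates 1 and 3, the rule that names clusters, the leaving out of single cells, and the settings without the cluster led by Gm42418, without clusters with more markers of another class, and with free RNA subtracted. The same holds for the measures that sum up results without a test. Single cells were left out with fewer than 3 of 7 CD8 T cell markers, or with over 0.5% of UMIs from 106 markers of other classes that stayed under 20 CPM in the mGluR-negative libraries. Genes among those markers fall with this filter by construction. Several thresholds were looked at before these were chosen. The T-like clusters include 2 whose leading genes against all other clusters hold more markers of another class than of T cells. The one led by Gm42418 held 0.651%, 45.4%, 18.2%, 44.9%, 0.0887% and 2.21% of the T-like cells in the library order above, and the other 0.508%, 2.52%, 0.553%, 2.54%, 5.03% and 2.12%.

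The edgeR step was tested on simulated counts with 200 changed genes. For brain mGluR-positive against brain mGluR-negative (8315 genes tested) it recovered 17%, 80.4%, 93.8% and 95.8% of genes changed by a log2 of 1, 2, 3 and 4, with 7 false calls among 8126 unchanged genes. Against spleen mGluR-positive (8525 genes) it recovered 15.6%, 78.7%, 87.5% and 97.7%, with 8 false calls among 8341. Changes near a log2 of 1 are thus mostly missed with this design and depth. The simulated counts were drawn with the shared spread that the fit assumes. The false calls therefore say nothing about genes whose own spread between libraries is wide. Alternatives covered the scaling, the test (DESeq2 1.42.0 Wald), the filter, the replicates, the cells summed, cell calling, the mitochondrial limit, doublets, depth, the offset and the resolution.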

Results

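The series measured messenger RNA in single CD8 T cells from C57BL/6J mice infected with the ME49 strain of Toxoplasma gondii, a parasite that persists in the brain. CD3+CD8+ cells were taken from brain or spleen 3 weeks after infection and sorted by surface staining for the metabotropic glutamate receptors mGluR1 and mGluR5. The series title concerns memory, interferon gamma and perforin. Groups were formed by title: brain double negative (1 library), brain double positive (3 libraries), spleen double negative (1 library) and spleen double positive (1 library). They are called mGluR-negative and mGluR-positive here. The deposited counts held 37351522 UMIs (unique molecular identifiers, each standing for 1 captured transcript) in the brain mGluR-negative library. The brain mGluR-positive replicates 1, 2 and 3 held 3795821, 8690531 and 3905561. The spleen held 184803312 UMIs in the mGluR-negative and 80955694 in the mGluR-positive library.

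Brain mGluR-positive replicates 1 and 3 shared 293 of their 300 richest barcodes, and no other pair of libraries shared any of its 300 richest. Over 9816 genes their counts differed with a chi-square per degree of freedom of 0.108, against 11.2 between replicates 1 and 2. They therefore differed by less than the sampling noise and were counted as 1 sample, at the mean of their counts, so that the brain mGluR-positive group has n = 2. The labels do not say whether libraries came from separate animals. The p-values rest on the spread between these samples pooled over all genes, not on each gene's own spread. A gene whose 2 positive samples differ widely can therefore still pass. Every other group has n = 1.

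After calling and filtering, 6355 cells were kept from the brain mGluR-negative library and 128, 211 and 127 from the brain mGluR-positive replicates 1, 2 and 3. The spleen gave 13721 mGluR-negative and 2382 mGluR-positive cells. The design text states 7676 brain mGluR-negative cells, 324, 570 and 334 for the positive replicates, and 16091 and 2502 for the spleen. Clusters were called T-like where at least 3 of 7 CD8 T cell markers were each detected in at least 0.5 of the cells and no other class had more markers among the leading genes against clusters that lacked those markers. T-like cells made up 99.2% of the brain mGluR-negative cells (exact binomial 95% interval 98.9 to 99.4) and 98.6% of the spleen mGluR-negative cells (98.4 to 98.8). They made up 93.0% (87.1 to 96.7) and 85.8% (80.3 to 90.2) in brain mGluR-positive replicates 1 and 2, but 45.6% (43.6 to 47.7) in the spleen mGluR-positive library. Leaving out 2 clusters whose leading genes against all others held more markers of another class kept 62, 147 and 1040 T-like cells there. The mGluR-negative libraries kept 6228 in brain and 12841 in spleen. Intervals here and below cover counting error only.

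**Figure D1:**
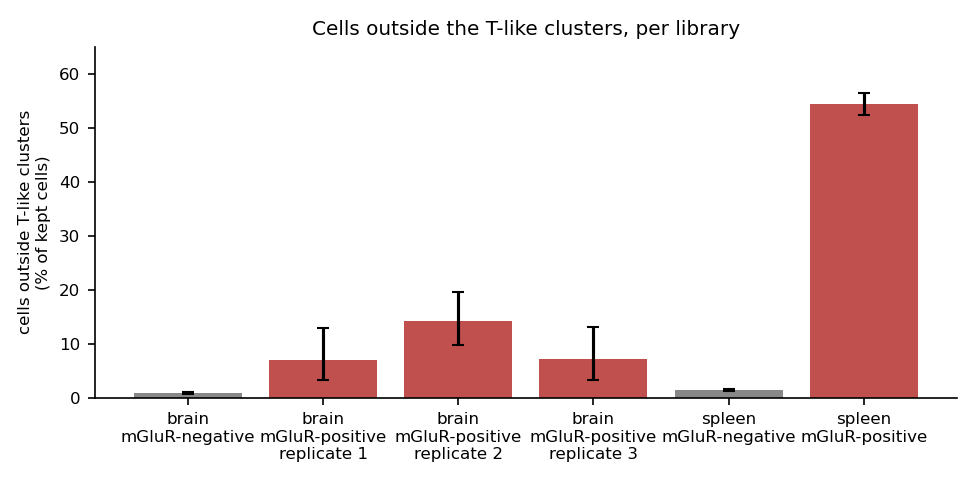
Cells outside the T-like clusters, in percent of kept cells, for each of the 6 libraries; bars are the share and error bars the exact 95% binomial interval. The spleen mGluR-positive library stands at 54.4%, the brain mGluR-positive replicates 1 and 2 at 7.03% and 14.2%, and both mGluR-negative libraries at 1.37% or less.

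In the spleen mGluR-positive library the other cells were mostly B cell-like (925 cells, 38.8%, 36.9 to 40.8), followed by monocyte or macrophage-like (173 cells, 7.26%), dendritic cell-like (118, 4.95%) and neutrophil-like cells (70, 2.94%), with 8 mast cell or basophil-like cells. The spleen mGluR-negative library held 136 B cell-like cells (0.991%, 0.832 to 1.17). In the brain, mGluR-positive replicates 1 and 2 held 4 and 13 monocyte or macrophage-like cells, 4 and 6 endothelial cell-like cells, and 1 and 10 dendritic cell-like cells, whereas the mGluR-negative library held 50 dendritic cell-like cells among 6355. The mGluR-positive libraries also lost more called cells to the limit of 10% mitochondrial UMIs: 24.7% and 19.1% in brain replicates 1 and 2 and 36.8% in spleen, against 0.06% and 0.03% in the mGluR-negative libraries. All comparisons below use UMIs summed over T-like cells. These comprised 6301 brain mGluR-negative cells (30278345 UMIs), 119 and 181 brain mGluR-positive cells in replicates 1 and 2 (930186 and 1302516 UMIs), and 13533 and 1087 spleen cells (135587953 and 9398740 UMIs).

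Transcripts of Grm5, which encodes mGluR5, were examined first. Grm5 (ENSMUSG00000049583, mm10 chromosome 7, 87584168 to 88134907, plus strand) had 6 UMIs in the T-like cells of brain mGluR-positive replicate 1, or 6.45 CPM (counts scaled by each library's total; exact Poisson interval 2.37 to 14), and 0 in replicate 2. It had no UMI in the T-like cells of the brain mGluR-negative library, where a count of 0 allows up to 0.122 CPM. In spleen, 1 Grm5 UMI was found in the mGluR-positive T-like cells (0.106 CPM, 0.00269 to 0.593) and 0 in the mGluR-negative cells. Of the 6 UMIs of replicate 1, 5 lay in 2 cells with no UMI of the 7 CD8 T cell markers and with 60 and 114 UMIs of neuron markers. The remaining UMI was in a cell with all 7 markers. When single cells with under 3 of these markers or with RNA of other cell classes were left out, 1 Grm5 UMI remained in replicate 1 and 0 in the spleen mGluR-positive library. Over all barcodes, empty droplets included, Grm5 reached 10 CPM (38 UMIs) and 5.75 CPM (50 UMIs) in brain mGluR-positive replicates 1 and 2, 0.0268 CPM (1 UMI) in brain mGluR-negative, and 0.124 CPM (10 UMIs) in spleen mGluR-positive.

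**Figure D2:**
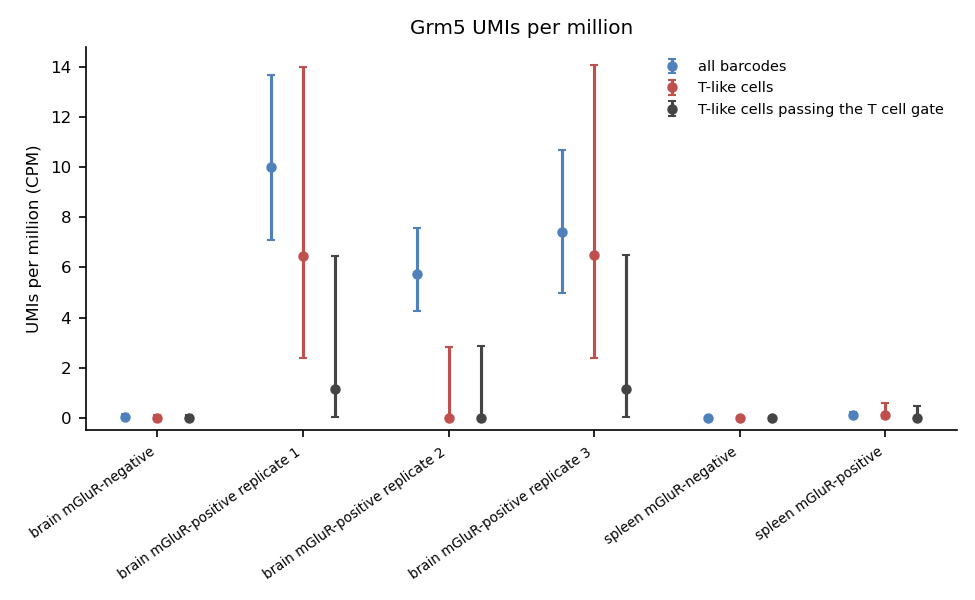
Grm5 in CPM for each of the 6 libraries, summed over T-like cells, over T-like cells that passed the T cell marker filter, or over all barcodes; error bars are exact 95% Poisson intervals. In T-like cells Grm5 stands at 6.45 CPM in brain mGluR-positive replicate 1 and at 0 in replicate 2.

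In order to ask how brain CD8 T cells that stained for both receptors differed from those that stained for neither, the T-like sums were compared with edgeR's quasi-likelihood test (2 distinct libraries against 1). Of 8618 genes tested, 57 passed a Benjamini-Hochberg adjusted p of 0.05, 51 higher and 6 lower in mGluR-positive cells. The heat shock genes Hspa1a and Hspa1b, the T cell activation receptor Tnfrsf4 (OX40) and the glycolytic enzyme gene Hk2 rose, and the NK receptor gene Klra7, the Fc receptor adaptor Fcer1g and the lectin gene Lgals3 fell. Among the genes in the series title, neither Ifng nor Prf1 passed the test. The largest increases were in genes of brain tissue, led by Ttr, which encodes the choroid plexus product transthyretin. Of the 51 genes called higher, 41 had over 3 times the CPM in replicates 1 and 3 as in replicate 2, 2 the reverse, and 8 lay within 3 times.

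Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321, plus strand) was at 2076 CPM in replicates 1 and 3 and 220 in replicate 2, against 0.132 in mGluR-negative cells (log2 fold change 12.76, SE 0.80, edgeR adjusted p = 3.03e-53). The choroid plexus gene Enpp2 (10.14, SE 0.59), Meg3 and Snhg11, long noncoding RNAs abundant in neurons, the astrocyte gene Clu, the lipid carrier gene Apoe (4.41, SE 0.66) and the brain cytoplasmic RNA Bc1 (5.81, SE 0.70) rose as well. All stood higher in replicates 1 and 3 than in replicate 2: Enpp2 at 365 and 14.6 against 0.132 CPM, Meg3 at 318 and 2.303 (3 UMIs) against 1 UMI, Clu at 137.5 and 0.768 (1 UMI) against 2 UMIs, Snhg11 at 120 and 3.07 (4 UMIs) against 3 UMIs, Apoe at 48 and 3.84 against 0.991 CPM, and Bc1 at 53.4 and 1.535 (2 UMIs) against 0.396 CPM. The UMIs of Ttr lay in 4 of 119 T-like cells of replicate 1 and in 1 of 181 of replicate 2. Empty droplets held Ttr at 968 and 55.5 CPM in replicates 1 and 2 and 18.1 in the mGluR-negative library. Without cells of few T cell markers or other-class RNA, 41 genes passed (36 higher, 5 lower; 38 of them among the 57), Bc1 did not (edgeR adjusted p = 0.868), and Ttr, Enpp2, Meg3, Snhg11, Clu and Apoe were too low to be tested. Ttr, Enpp2, Meg3, Clu and Apoe are among the markers by which cells were left out, so their loss was built in.

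Other large increases were Klkb1 (7.32, SE 0.57), which encodes plasma kallikrein, the transcript model AC160336.1 (4.69, SE 0.40, edgeR adjusted p = 7.54e-28) and the lysosomal protease gene Ctsl (3.82, SE 0.46). All 3 passed without those cells too. Klkb1 stood at 92.8 CPM in replicates 1 and 3, 0.768 in replicate 2 and 0.231 in mGluR-negative cells, and its empty-droplet level in replicate 1 was 2484 CPM. AC160336.1 stood at 252, 13.1 and 4.36 CPM. Ctsl stood at 58.25, 14.6 and 2.18 CPM, and 91.1% of the replicate 1 UMIs and 73.7% of the replicate 2 UMIs lay in the 2 richest cells.

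Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, minus strand) rose by 3.17 on the log2 scale (SE 0.36, edgeR adjusted p = 3.96e-15), and Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238, minus strand) by 2.96 (SE 0.36, 1.10e-13). These genes are near-identical copies, so the split of counts between them is uncertain. Hspa1a stood at 141 CPM in replicates 1 and 3 but 7.68 in replicate 2, beside 6.94 in mGluR-negative cells. Its empty-droplet level was 58.7 and 93.8 CPM in replicates 1 and 2 and 5.28 in the mGluR-negative library. Hspa1b stood at 190, 34.6 and 12.4 CPM, and at 45.5, 29.7 and 11.9 CPM in those empty droplets. They were the only members called of 23 tested of the list of immediate early and dissociation stress genes, with none lower (3 higher when adjusted over the list alone). Jun was at 1.00 (SE 0.33, edgeR adjusted p = 0.192). This list's median was 0.07 (camera adjusted p = 0.0131, and adjusted p = 0.807 with an estimated correlation). With 1 residual degree of freedom the estimated correlation leaves almost no power, here and below.

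Tnfrsf4 (ENSMUSG00000029075, chromosome 4, 156013843 to 156016612, plus strand) rose by 2.04 (SE 0.34, edgeR adjusted p = 1.02e-06), from 23.5 CPM to 147 in replicates 1 and 3 and 73.7 in replicate 2. It was the 1 member called among 19 tested of the T cell receptor (TCR) activation list, and also 1 when adjusted over the list alone. Egr3 (1.08, SE 0.41) and Il2ra (0.95, SE 0.36) did not pass. The list's median was 0.53 (camera adjusted p = 0.00104, and adjusted p = 0.807 with an estimated correlation). The glycolytic enzyme gene Hk2 rose by 1.40 (SE 0.38, edgeR adjusted p = 0.0353; 63.6 and 17.7 against 13.1 CPM). It was the 1 glycolysis gene called of 17 tested, in either adjustment, and this list's median of -0.03 and mean of 0.16 differed in sign (camera adjusted p = 0.523).

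Klra7 (ENSMUSG00000067599, chromosome 6, 130218605 to 130233322, minus strand), a member of a family of closely related genes, fell by 2.09 (SE 0.39, edgeR adjusted p = 2.57e-05), from 42.6 CPM to 1.08 in replicates 1 and 3 and 19.2 in replicate 2. Fcer1g (ENSMUSG00000058715, chromosome 1, 171229572 to 171234365, minus strand) fell by 1.67 (SE 0.37, 0.00135), from 45.9 to 16.2 and 16.1 CPM. It was higher instead, by 2.65, when all kept cells were summed. Fcer1g lay in 5 of 119 and 6 of 181 T-like cells of replicates 1 and 2, against 263 of 6301 mGluR-negative cells. These positive cells held 15 and 21 UMIs, with 80% and 71.4% in the 2 richest. Klra7 lay in 1 and 5 cells of those replicates, against 238 mGluR-negative cells. Both falls thus rest on few carrier cells. Lgals3 fell by 1.21 (SE 0.33, 0.0475), from 288 to 110 and 167 CPM. Hmox2, a heme oxygenase gene, fell by 1.16 (SE 0.32, 0.0475; 21.03 and 36.9 against 59.6 CPM). With cells of other-class RNA or few T cell markers left out its change was -1.145, which did not pass (edgeR adjusted p = 0.0796). With the largest share of free RNA subtracted, 0 genes were called lower. Fcer1g was the 1 member of 17 tested that changed in the memory CD8 list (2 lower when adjusted over the list alone; median -0.18, camera adjusted p = 0.0418, and adjusted p = 0.807 with an estimated correlation).

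Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, plus strand), which encodes interferon gamma, was at 211 ± 40.1 CPM (SD, n = 2) in mGluR-positive and 281 CPM in mGluR-negative cells (log2 fold change -0.57, SE 0.35, edgeR adjusted p = 0.609). Prf1 (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680, plus strand), which encodes perforin, was at 93.6 ± 16.4 CPM (SD, n = 2) against 109 (-0.37, SE 0.32, edgeR adjusted p = 0.761). The granzyme genes Gzmb (-0.68, SE 0.42), Gzma (-1.26, SE 0.42) and Gzmk (-0.50, SE 0.35), the chemokine gene Ccl5 (-1.11, SE 0.45) and Klrd1 (-0.91, SE 0.35) did not pass either. Tnf was at 1.24 (SE 0.36, edgeR adjusted p = 0.0720; 78.7 CPM in replicates 1 and 3, 17.7 in replicate 2 and 17.3 in mGluR-negative cells) and passed without cells of few T cell markers or other-class RNA (1.31, edgeR adjusted p = 0.0416). None of the 30 cytotoxic effector genes passed by edgeR over all genes, where 842 of 8618 genes had an unadjusted p under 0.05 and DESeq2's Wald test called 22 genes in all. Adjusted over the list alone, 1 was higher and 2 were lower. The list's median was -0.56 (camera adjusted p = 7.59e-07, and adjusted p = 0.807 with an estimated correlation), with 26 of 30 members lower.

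Oxidative phosphorylation (0 of 32 called, median -0.52, camera adjusted p = 1.72e-06) and ribosomal protein genes (0 of 28, median -0.50, 0.00115) were lower as lists, but not with an estimated correlation (adjusted p = 0.807 and 0.821). Against random lists of matched expression the median of the oxidative phosphorylation list lay at the percentile 0.885 and that of the ribosomal protein list at 9.07, which is inside their central 95% (-0.55 to -0.10). The cytotoxic effector (0.01), Gq and calcium signalling (99.9), TCR activation (99.99) and class II lists (99.9) lay outside the central 95% of such lists, and the memory CD8 (30.6) and immediate early lists (80.2) inside it. Median mitochondrial shares were 1.26% in mGluR-negative and 2.62% and 2.53% in mGluR-positive T-like cells, and the nuclear RNA Malat1 stood at 17740 against 28520 and 29460 CPM. Ndufb8 (-0.90, SE 0.34) and Rpl5 (0.95, SE 0.42) were among their members that did not pass. Genes of Gq and calcium signalling, the pathway downstream of both receptors, had a median of 0.44 (0 of 17 called; camera adjusted p = 0.0418, and adjusted p = 0.807 with an estimated correlation), with Itpr2 at 0.71 (SE 0.33) and Nfatc2 at 0.72 (SE 0.34). Class II antigen presentation had a median of 1.95 (camera adjusted p = 0.0013, and adjusted p = 0.807 with an estimated correlation), with Cd74 called of 5 tested (2 higher when adjusted over the list alone). Cd74 rose by 1.96 (SE 0.34, edgeR adjusted p = 3.81e-06; 108 and 24.6 against 14.5 CPM), but was at 0.18 (0.921) without cells of other-class RNA or few T cell markers, and the list's median was then 0.18. H2-Aa and H2-Ab1 of this list are among the markers by which those cells were left out. The empty droplets of replicates 1 and 2 held Cd74 at 460 and 1434 CPM, against 150 in the mGluR-negative library.

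No member was called, over all genes or over the list alone, among 9 glutamate transport and metabolism genes (median 0.28, camera adjusted p = 0.488), 18 resident memory genes (median 0.07, mean -0.01, 0.964; Cd69 0.48, SE 0.38), 17 exhaustion genes (0.15, 0.964; Pdcd1 -0.56, SE 0.33), 25 proliferation genes (-0.17, 0.12; Stmn1 -0.99, SE 0.37), 18 chemokine receptor and homing genes (median -0.09, mean 0.02, 0.488) and 17 apoptosis genes (-0.02, 0.388; Bax -0.80, SE 0.33). Among 16 naive and central memory genes (median -0.08, mean 0.03, 0.388) none was called over all genes and 2 were lower over the list alone, with Klf2 at -1.09 (SE 0.32, edgeR adjusted p = 0.0720). Among 32 interferon response genes (0.06, 0.958) 1 was higher over the list alone, with Iigp1 at 1.14 (SE 0.32, edgeR adjusted p = 0.0521). Of 23 glutamate receptor genes only Gria2 had enough counts to be tested and it did not pass (22 UMIs in replicate 1, 0 in replicate 2, 1 in mGluR-negative cells). Cd8a (-0.10, SE 0.41), Cd8b1 (-0.16, SE 0.41), Tcf7 (-0.03, SE 0.34), Il7r (-0.15, SE 0.32), Klrg1 (-0.43, SE 0.32), Cx3cr1 (-0.64, SE 0.32), Cxcr6 (-0.33, SE 0.37), Itgae (-0.20, SE 0.38) and Tox (0.18, SE 0.39) did not pass, and Cd4 (2.70 and 3.07 CPM against 1 UMI) was too low to be tested. Of 13 mitochondrial genes 2 rose (mt-Nd6 and mt-Nd3), and 0 of 91 ribosomal protein genes and 0 of 10 T cell receptor segments changed by edgeR.

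The cluster led by Gm42418, a model that overlaps ribosomal RNA, held 45.4% and 18.2% of the T-like cells of mGluR-positive replicates 1 and 2 and 0.651% of the mGluR-negative ones. Gm42418 itself, which was chosen after its values were seen, was at 41880 and 7084 CPM against 3478. Its empty-droplet level was 113100 and 132300 CPM, against 10790 in the mGluR-negative library. Without this cluster and another, which held more markers of another class than of T cells among their leading genes against all other clusters, 48 genes passed (41 among the 57). With replicates 1 and 3 counted as separate libraries edgeR called 0 genes (2305 at an unadjusted p under 0.05), and DESeq2's Wald test on the merged libraries called 22, of which 8 were among the 57.

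**Figure D3:**
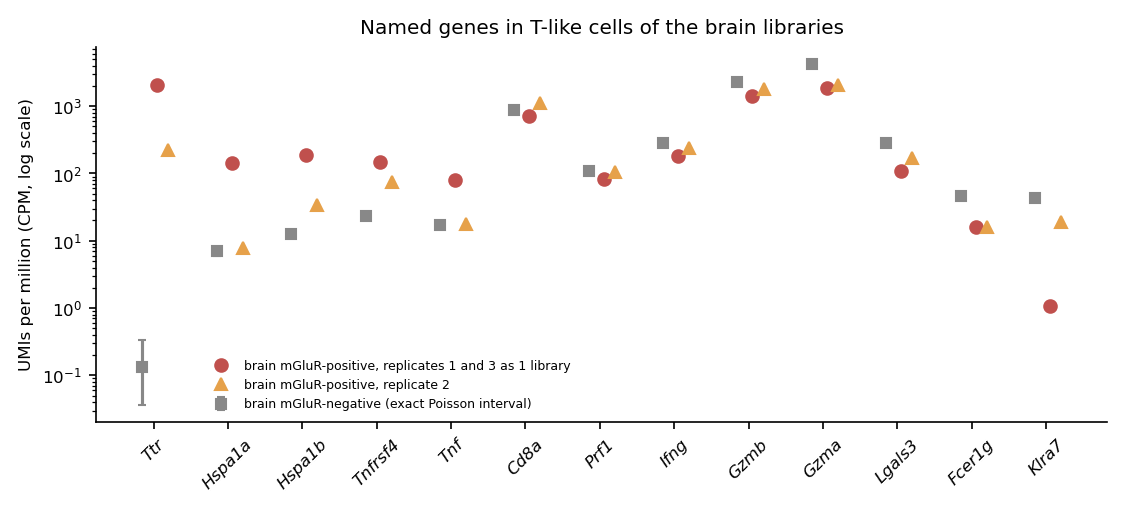
Levels of named genes in T-like cells of the brain libraries, in CPM on a log axis; squares are the mGluR-negative library with its exact 95% Poisson interval, circles the mGluR-positive replicates 1 and 3 as 1 library and triangles replicate 2. Hspa1a stood at 141 CPM in replicates 1 and 3 and at 7.68 in replicate 2, and Ifng at 183 and 240 CPM against 281.

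To compare shares of cells at one depth, each T-like cell was thinned to 1000 UMIs, which left out 1 cell. Ifng was then detected in 16.5% of brain mGluR-negative cells (15.6 to 17.5) and in 17.8% (11.4 to 25.9) and 13.8% (9.14 to 19.7) of cells of mGluR-positive replicates 1 and 2. Counting replicates 1 and 3 as 1, the positive mean was 15.8% ± 2.82 (SD, n = 2; two-sided exact permutation p = 1). With 2 against 1 the smallest exact p is 0.333. Without thinning, at median depths of 3891, 5868 and 6189 UMIs, the shares were 43.5%, 48.7% and 51.4%. Among cells outside the T-like clusters the thinned share was 0 of 54, 0 of 9 and 0 of 30 cells. Prf1 was detected in 10.7%, 10.2% and 7.74% of thinned T-like cells (35.03%, 37.8% and 40.3% unthinned), Gzmb in 59.7%, 44.1% and 35.9% (80.3%, 69.7% and 64.6%), and Gzma in 48.5%, 29.7% and 31.5% (61.0%, 48.7% and 42.0%). Of the 22 genes examined this way, 8 had a lower thinned share in both positive libraries than in the negative one and 2 a higher share. For Gzmb and Gzma the exact permutation p was 0.333, the smallest this design gives.

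In order to compare the tissues, mGluR-positive T-like cells of brain were set against those of spleen with edgeR (2 distinct libraries against 1). Of 8873 genes, 627 passed, 325 higher and 302 lower in brain. The TCR target gene Nr4a2, the inhibitory receptor gene Ctla4, the resident memory gene Rgs16 and the interferon response gene Rsad2 rose, as did Ifng and Gzmb. Of 22 naive and central memory genes 19 fell, among them Ccr7, Dapl1 and Igfbp4. Genes of B cells and myeloid cells such as Cd79a and S100a8 also fell, in a spleen library where 54.4% of kept cells lay outside the T-like clusters. Most brain cells lay in a cluster led by Isg20, Ifit1 and Gzmb (27.7% and 44.8% of replicates 1 and 2) or in the one led by Gm42418, and the largest spleen clusters were one led by Kcnj8 and S1pr5 (25.6%) and one led by mitochondrial genes (24.3%).

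Nr4a2 (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003, minus strand), an immediate target of TCR signalling, was at 140 and 99.8 CPM against 3.19 (4.97, SE 0.44, edgeR adjusted p = 3.85e-27). Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832, plus strand), an inhibitory receptor, was at 160 and 217 CPM against 6.28 (4.67, SE 0.43, 4.59e-25). In the exhaustion list 8 of 17 genes rose and 1 fell (10 and 3 adjusted over the list alone; median 1.07), with Pdcd1 at 2.97 (SE 0.46) and Lag3 at 2.33 (SE 0.37). In the resident memory list 10 of 18 rose and 0 fell (14 and 1 over the list alone; median 1.496), with Rgs16 at 4.59 (SE 0.49), Cxcr6 at 2.05 (SE 0.39), Rgs1 at 2.87 (SE 0.41) and Itga1 at 2.24 (SE 0.36), while Itgae (0.81, SE 0.42) and Cd69 (0.98, SE 0.38) did not pass. In the TCR activation list 9 of 19 rose (13 and 1 over the list alone; median 1.11), with Nr4a1 at 3.46 (SE 0.42), Il2ra at 3.28 (SE 0.46) and Tnfrsf4 at 2.23 (SE 0.36). In the interferon response list 17 of 32 rose (18 and 1 over the list alone; median 1.16), with Rsad2 at 4.37 (SE 0.53), Ifit3 at 3.07 (SE 0.37) and Isg15 at 2.14 (SE 0.38). Ifit3 was at -0.17 in the largest brain T-like cluster, which held 2 spleen cells. The camera adjusted p of these 4 lists ran from 3.03e-16 to 1.78e-09, and each was at an adjusted p = 0.382 with an estimated correlation.

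Ifng rose by 1.75 (SE 0.36, edgeR adjusted p = 4.79e-05; 183 and 240 against 53.9 CPM) and Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand) by 2.86 (SE 0.49, 4.75e-07; 1403 and 1800 against 188 CPM). Gzmk (1.86, SE 0.36), Tnf (1.48, SE 0.39) and the chemokine genes Ccl4 (3.06, SE 0.49) and Ccl3 (2.20, SE 0.36) rose, whereas Cx3cr1 (-2.04, SE 0.33) and S1pr5 (-2.56, SE 0.36), receptors of circulating effector cells, fell. Prf1 (-0.18, SE 0.33, edgeR adjusted p = 0.916), Gzma (-0.39, SE 0.44), Ccl5 (-0.14, SE 0.48) and Klrg1 (-0.53, SE 0.32) did not pass. In all, 9 of 29 cytotoxic effector genes rose and 4 fell (11 and 5 adjusted over the list alone; median 0.26, camera adjusted p = 0.015, and adjusted p = 0.598 with an estimated correlation). Gzma was higher in brain, by 1.43, when only the largest brain T-like cluster was summed, which held 2 spleen cells.

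In the naive and central memory list 19 of 22 genes fell and none rose (19 lower and 1 higher over the list alone), with Dapl1 at -5.46 (SE 0.42; 11.9 and 0 against 192 CPM), Ccr7 at -5.05 (SE 0.44; 5.93 and 0.768 against 91 CPM) and Tcf7 at -2.62 (SE 0.33). Tcf7 was at 6.358 in the largest brain T-like cluster, which held 2 spleen cells. Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392, plus strand) had 0 UMIs in the brain cells and 73.7 CPM in spleen, at least 22.7-fold lower against a floor of 3 counts in the shallowest library (3.247 CPM). The list's median was -2.47, and -2.47 with Igfbp4 and Il6ra at their bounds (camera adjusted p = 1.66e-42, and adjusted p = 0.382 with an estimated correlation). Il7r fell by 1.19 (SE 0.33). The medians of the memory CD8 and homing lists lay inside the central 95% of random lists (percentiles 27.3 and 28.2). In the memory CD8 list 1 of 18 rose and 6 fell, among them Id3, Slamf6 and Fcer1g (5 higher and 6 lower over the list alone; median -0.04, mean -0.54, camera adjusted p = 0.0097, and adjusted p = 0.392 with an estimated correlation), and in the homing list 2 of 19 rose and 6 fell, among them S1pr1 at -2.32 (5 and 6 over the list alone; median -0.03, camera adjusted p = 0.00404, and adjusted p = 0.392 with an estimated correlation).

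The immediate early and dissociation stress list had 10 of 23 genes higher (12 over the list alone; median 0.90), among them Hspa1b (3.70, SE 0.39), Hspa1a (4.21, SE 0.42) and Dusp2 (2.32, SE 0.41), with a camera adjusted p of 2.73e-10 and an adjusted p = 0.382 with an estimated correlation. The labels describe enzyme digestion of brain and not of spleen. Glycolysis had 5 of 17 higher (8 over the list alone; median 0.74, camera adjusted p = 7.56e-06, and adjusted p = 0.444 with an estimated correlation), with Hif1a at 1.84 (SE 0.38) and Hk2 at 2.13 (SE 0.42). Apoptosis had 5 of 17 higher and 1 lower, the same over the list alone (median 0.47, 0.0186, and adjusted p = 0.424 with an estimated correlation), with Cdkn1a at 2.39 (SE 0.44) and Bcl2 at -2.04 (SE 0.33). Proliferation had 1 of 25 higher, Aurkb at 1.13 (SE 0.38), and 0 over the list alone (median 0.36, 0.0382, and adjusted p = 0.424 with an estimated correlation). Glutamate transport and metabolism had 2 of 9 higher, Got1 (1.29, SE 0.36) and Slc3a2 (1.09, SE 0.34), in either adjustment (median 0.52, camera adjusted p = 0.0694), and Gq and calcium signalling 1 of 17, Itpr1 (1.36, SE 0.34), in either adjustment (median 0.25, 0.161). Slc3a2 was at -0.89 in the largest brain T-like cluster, which held 2 spleen cells. Of the glutamate receptors Gria2 was tested; it passed over the list alone and not over all genes. No gene of oxidative phosphorylation (32 tested, median -0.17, 0.161) or of the ribosomal protein list (28 tested, median -0.68, camera adjusted p = 4.08e-06, and adjusted p = 0.511 with an estimated correlation) passed by edgeR, where 1439 of 8873 genes had an unadjusted p under 0.05 and DESeq2's Wald test called 224.

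Genes of other cell classes were among the largest differences. Slpi, Mzb1, Cd79a, Ly6d, S100a9, S100a8, Car1, Ms4a1 and Cd24a had 0 UMIs in the brain mGluR-positive cells and 437, 187, 143, 121, 118, 101, 94.8, 59.0 and 45.5 CPM in spleen, at least 134.6-fold lower for Slpi and at least 14.02-fold lower for Cd24a against the same floor. Of the 4109 Slpi UMIs in spleen, 69.8% lay in the 2 richest cells and 234 in cells with T cell markers. Class II antigen presentation had 5 of 7 genes lower (5 over the list alone; median -3.78, camera adjusted p = 2.62e-23, and adjusted p = 0.382 with an estimated correlation), with H2-Aa at -4.39 (SE 0.38). Of 26 immunoglobulin genes 24 fell, and Cd4 fell by 3.34 (SE 0.58). In the other direction Ttr had 0 spleen UMIs and stood at 2076 CPM in brain replicates 1 and 3 and 220 in replicate 2, with 99.9% and 100% of the UMIs of replicates 1 and 2 in the 2 richest cells. Of 13 mitochondrial genes 7 fell (median of these -1.58), beside median mitochondrial shares of 2.62% and 2.53% in the brain and 6.15% in the spleen cells. Without cells of few T cell markers or other-class RNA 600 genes passed (520 among the 627), and without both clusters with more leading markers of another class than of T cells 430 (408 among the 627). Without the mitochondrial limit 160 genes passed, 41.2% of them higher against 51.8%.

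**Figure D4:**
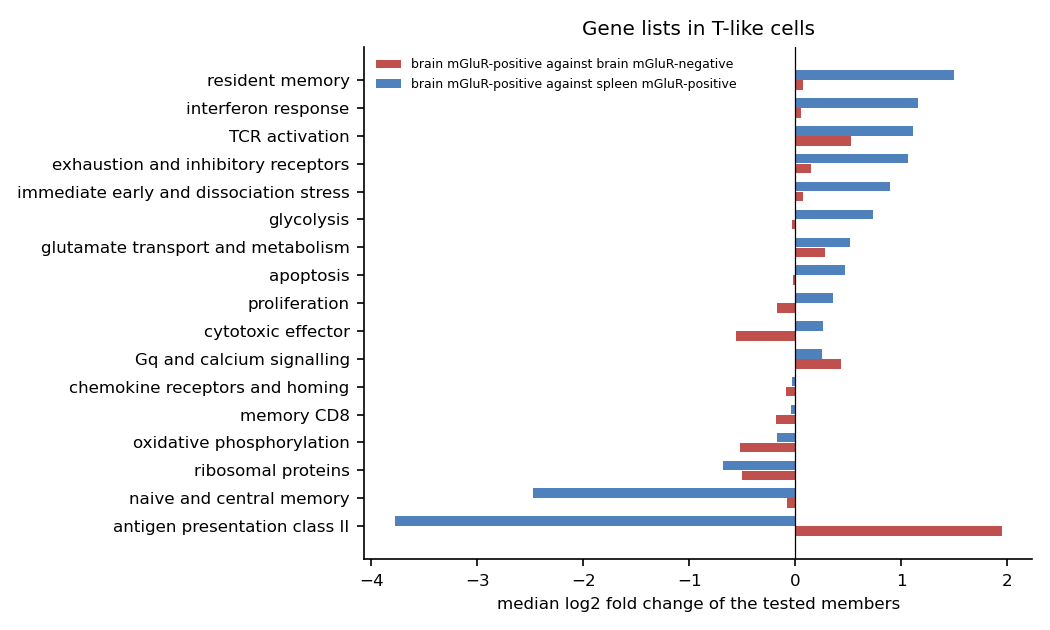
Median log2 fold change of the tested members of each gene list in T-like cells, for brain mGluR-positive against brain mGluR-negative and against spleen mGluR-positive cells. Against spleen, the naive and central memory list stood at -2.47 and the resident memory list at 1.496; against brain mGluR-negative cells the cytotoxic effector list stood at -0.56.

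The same sort was compared in spleen, where each group was 1 library, so there is no replicate check and the values compare those libraries. Genes of red cells, neutrophils and B cells were higher in the mGluR-positive T-like cells. Jun, Prf1 and other effector genes were lower, as were Cd8a and Cd8b1. The median log2 ratio of all 11696 genes with at least 100 UMIs was -0.17 (CPM + 1). Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096, minus strand), a hemoglobin gene, was at 56.5 against 0.170 CPM (log2 ratio 5.62, counting interval 5.40 to 5.82) and at 2.14 without cells of few T cell markers or other-class RNA. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035, plus strand), a neutrophil protein gene, was at 101 against 1.17 CPM (5.56, 5.34 to 5.77), and at 951 CPM in the library's empty droplets. Car1 (5.40), S100a9 (5.28), Hbb-bt and Hba-a1 (5.16 each), Mzb1 (4.70), Cd24a (4.63), Car2 (4.60) and Ly6d (4.57) followed. Without cells of few T cell markers or other-class RNA these were at 5.08, 5.32, 3.399, 3.115, 3.27, 3.54, 3.88 and 4.03 in the same order, and S100a8 at 5.62. The hemoglobin genes are near-identical to other copies, so their split is uncertain. Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221, minus strand) was at 23.5 against 0.479 CPM (4.05, 3.74 to 4.34). Class II genes had a median of 3.51 (6 of 7 higher by 1 or more), above all of 10000 random lists of matched expression (percentile 100), and 23 of 25 immunoglobulin genes and 10 of 13 mitochondrial genes were higher by 1 or more.

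Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222, minus strand) was at 92.8 against 268 CPM (-1.52, -1.63 to -1.41), and the immediate early list, with 5 of 23 genes lower by 1 or more, had a median of -0.53 (percentile 0). Msc, Kcnc1, Hspa1a, Wdr66, Flot1, Rgs11, Pim3, Esm1 and Ggt1 lay between -1.32 and -1.22 (-1.32 to -1.07 without cells of few T cell markers or other-class RNA). Prf1 was at 90.5 against 148.5 CPM (-0.71, -0.82 to -0.59), Gzma at -0.47 (-0.50 to -0.45), Gzmb at -0.46 (-0.54 to -0.38), Gzmk at -0.44, Ccl5 at -0.52, Cx3cr1 at -0.40 and Klrg1 at -0.48, and the cytotoxic effector list at a median of -0.43 (percentile 0.01). Cd8a (-0.76, -0.82 to -0.71), Cd8b1 (-0.71, -0.75 to -0.67) and Itgae (-0.61) were lower too. The effector list's median was -0.33 without cells of few T cell markers or other-class RNA. In the full sums it fell by less than Cd8a and Cd8b1, so a fall particular to that list is not shown. Ifng was at 53.9 against 60.3 CPM (-0.16, -0.32 to -0.00), at 0.03 within the largest T-like cluster and at 0.05 with doublets kept. Within that cluster Klrg1 was at 0.0113 and Il7r at 0.0128. The intervals of Tnf (-0.22, -0.51 to 0.07), Cxcr6 (-0.12, -0.25 to 0.02), Pdcd1 (0.15, -0.35 to 0.64) and Tox (0.03) included 0, and Il7r (-0.27), Tcf7 (-0.26) and Cd69 (-0.25) were slightly lower. Without cells of few T cell markers or other-class RNA these 3 were at -0.09, -0.07 and -0.11, Ifng at -0.04, Cxcr6 at 0.07, Cx3cr1 at -0.25, Gzmk at -0.31, Cd8a at -0.58 and Prf1 at -0.78. At 1000 UMIs per cell Ifng was detected in 6.07% (4.73 to 7.66) of mGluR-positive and 5.51% (5.13 to 5.91) of mGluR-negative T-like cells, and Prf1 in 9.75% (8.05 to 11.7) and 15.4% (14.8 to 16.0). In cells of the mGluR-positive library outside the T-like clusters these shares were 0.463% and 0.695%. Without thinning, at median depths of 7232, 9062 and 6340 UMIs, the Ifng shares were 21.6%, 28.6% and 2.63%.

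Proliferation (median 0.61, percentile 100), oxidative phosphorylation (0.22, 100), exhaustion (0.12, 99.4) and resident memory (0.04, 99) lay above most random lists. Interferon response (-0.32, 1.31), memory CD8 (-0.33, 2.02), homing (-0.31, 3.05), glycolysis (-0.33, 3.31), naive and central memory (-0.26, 8.99), Gq and calcium signalling (-0.27, 11.6), apoptosis (-0.26, 17.8), glutamate transport (-0.26, 25.1), ribosomal protein (-0.11, 42.0) and TCR activation genes (median -0.07, mean 0.14, 88.0) followed. Of the glutamate receptors 2 reached 100 UMIs. Most spleen mGluR-negative cells lay in clusters led by Kcnj8 and S1pr5 (35.1%), by Ccr9 and Igfbp4 (24.1%) and by Dapl1 and Bcl2 (14.4%), against 25.6%, 8.10% and 8.28% of mGluR-positive cells, of which a further 24.3% lay in the cluster led by mitochondrial genes.

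The tissues were also compared within the mGluR-negative sort, again 1 library against 1. Ctla4, Rgs16, Ccl4, Gzmb and Ifng were among the genes higher in brain, and 19 of 22 naive and central memory genes were lower by 1 or more. The median of all 11769 genes was -0.21. Scaling by TMM factors (trimmed mean of M-values) moved this median by 0.16. Ifitm3 (ENSMUSG00000025492, chromosome 7, 141009586 to 141010770, minus strand), an interferon-induced membrane protein gene, was at 90.7 against 2.26 CPM (4.82, 4.65 to 4.98). Ctla4 (4.71), Tff1 (4.65), Ccl1 (4.62, 3 UMIs in spleen), Krt83 (4.58), Ifitm1 (4.53), Rgs16 (4.40), AA467197 (3.90) and Isg20 (3.73) followed. The largest T-like cluster of these libraries held 67 brain cells. Within it Ccl1 and Krt83 were at -0.0433 and Isg20 at -0.20. Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683, plus strand) was at 1782 against 113 CPM (3.97, 3.94 to 4.01). Gzmb was at 2297 against 259 CPM (3.14, 3.12 to 3.17) and Ifng at 281 against 60.3 CPM (2.20, 2.14 to 2.27), with Gzmk at 1.96, Cxcr6 at 2.32 and Pdcd1 at 3.45. Gzma (0.46), Ccl5 (0.51), Itgae (0.41), Cd8a (0.45) and Cd69 (0.31) differed less, and Tnf was at 0.07 (-0.11 to 0.24). Within the largest T-like cluster Itgae was at -2.655 and Cd8a at -0.21.

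Igfbp4 was at 0.363 against 95.2 CPM (-6.14, -6.37 to -5.84). Dapl1 (-5.69), Ccr7 (-5.18), Il6ra (-4.74), Tmem108 (-4.53), Nsg2 (-4.30), Slpi (-4.21), Rflnb (-4.15), Ccr9 (-4.13), Tcf7 (-2.74), Cx3cr1 (-1.72) and Il7r (-1.25) were lower in brain as well. Cx3cr1 was at 0.0124 within the largest T-like cluster of these libraries. For Slpi, 45.2% of its 2698 spleen UMIs lay in the 2 richest cells and 1471 in cells with T cell markers, and its ratio was -3.39 without cells of few T cell markers or other-class RNA. Prf1 (-0.45, -0.52 to -0.38), Klrg1 (-0.51), Cd8b1 (-0.54) and Tox (-0.84) were lower by less, and Cd4, with 1 UMI in brain, stood at 0.479 CPM in spleen (-0.52, -0.69 to -0.21). Among the lists, resident memory (1.55), proliferation (1.24), exhaustion (1.13), TCR activation (0.94) and cytotoxic effector genes (0.63; 9 of 30 higher and 4 lower by 1 or more) lay above all random lists, and interferon response (0.53, percentile 99.99), oxidative phosphorylation (0.58, 99.95), glycolysis (0.57, 99.9) and apoptosis genes (0.31, 99.7) above most. Naive and central memory (-2.34; 19 of 22 lower by 1 or more), class II (-1.36), homing (-0.49) and ribosomal protein genes (-0.34) lay below all random lists. Immediate early (0.18, 91.4), glutamate transport (median -0.12, mean 0.06, 28.4), memory CD8 (-0.09, 15.01) and Gq and calcium signalling genes (-0.35, 10.8) lay between, and 2 glutamate receptor genes reached 100 UMIs. Most brain cells lay in the cluster led by Isg20, Ifit1 and Gzmb (57.6%), which held 0.229% of the spleen cells. The values thus compare different clusters of one class.

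**Figure D5:**
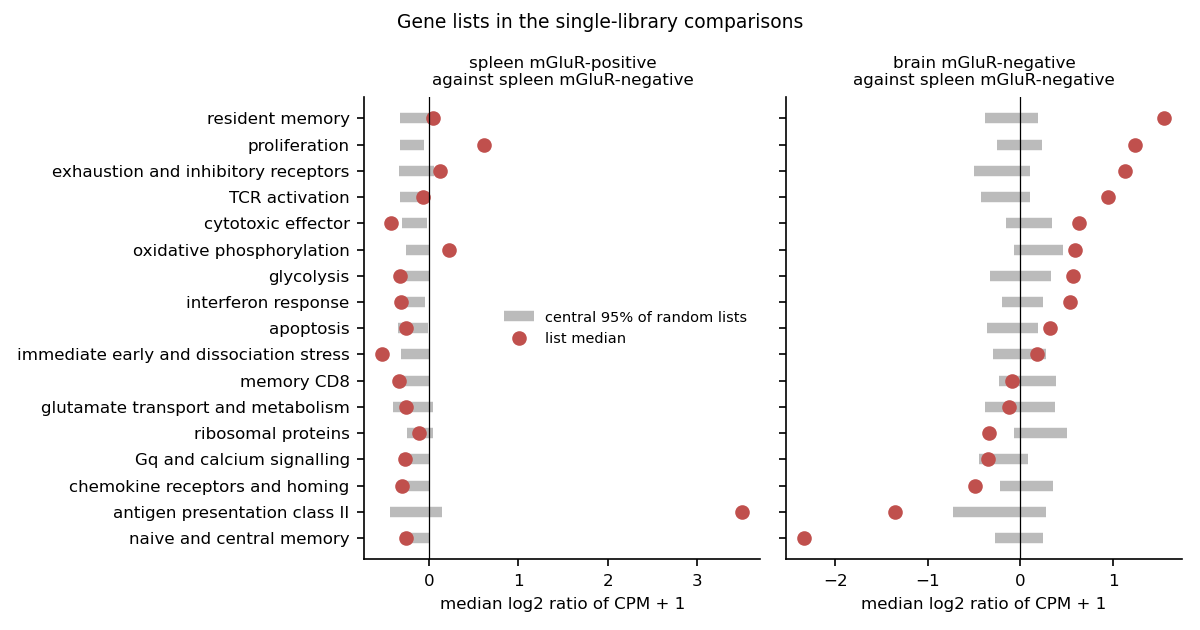
Median log2 ratio of CPM + 1 of each gene list (points) in both comparisons of 1 library with 1, with the central 95% of 10000 random lists of matched size and expression (grey bars). In spleen the class II list stood at 3.51, and in the mGluR-negative sort the naive and central memory list stood at -2.34.

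Because some labels call the spleen samples brain, free RNA was examined in droplets of 1 to 50 UMIs. Neuron markers made up 0.00284%, 0.0380% and 0.0385% of UMIs in brain mGluR-negative and mGluR-positive replicates 1 and 2, against 0.000834% and 0.00104% in spleen. Counting replicates 1 and 3 as 1 sample, all 3 brain samples lay above both spleen libraries. All brain-cell lists together gave 0.0499% (0.0475 to 0.0525) in brain mGluR-negative, 0.233% and 0.261% in mGluR-positive replicates 1 and 2, and 0.0580% and 0.0974% in spleen, so that 2 of 3 brain samples lay above both. Astrocyte and choroid plexus or ependymal markers did so in 3 of 3, oligodendrocyte markers in 2 and microglia markers in 1.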

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

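The tests of 9 of the 12 explanations below were set after the result was seen, and the tests of a general fall and of both cluster mixes before; a demand on resampled ranges, added later, left 3 readings open.

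The change from mGluR-negative to mGluR-positive cells differed between brain and spleen for 61 of 12889 genes by edgeR quasi-likelihood (Benjamini-Hochberg adjusted; 14 higher and 47 lower in brain; 33 without cells of few T cell markers or other-class RNA). The spleen has 1 library per group, so this rests on the spread of the brain mGluR-positive libraries. The brain change exceeded the spleen change, on the log2 scale, for AC160336.1 (4.04), Ctsl (3.50), Hspa1a (4.36), Hspa1b (3.74), Jun (2.20) and Klkb1 (4.11). In brain mGluR-positive replicates 1 and 2 the first 3 held 247 and 17, 56 and 19, and 130 and 10 UMIs. Hspa1b, Jun and Klkb1 held 176 and 45, 140 and 80, and 97 and 1. The brain change of Jun was not called, and its spleen log2 ratio was -1.52. The brain change was below the spleen change for Car2 (-2.23, and -5.12 without cells of few T cell markers or other-class RNA), Fcer1g (-3.50), H2-Aa (-2.39), H2-Ab1 (-2.52, and -5.00 without them), H2-Eb1 (-2.20), Klra7 (-2.97) and Ly6d (-11.43, a fitted value that is no bound, as brain mGluR-positive cells had 0 UMIs). Signals outside the T-like sums were cells outside the T-like clusters, at 7.03% and 14.2% in brain mGluR-positive replicates 1 and 2 and 54.4% in spleen mGluR-positive, and Grm5 over all barcodes at 10, 5.75 and 0.124 CPM in the same libraries.

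Brain-cell genes were higher in brain mGluR-positive T-like cells. For the 6 called genes of the brain-cell marker lists, the 10 richest cells held at least 99.96% of the UMIs of Clu, Enpp2, Meg3, Ptgds, Trf and Ttr in each distinct library, as a few cells of brain types, alone or joined to a T cell, would give. Free RNA in every droplet is argued against, since at most 9.274% of the cells expected from an even spread held a UMI. Transcription by the mGluR-positive T cells at large is argued against too, since at most 1.939% (upper 95% limit) of cells with T cell markers held 2 or more UMIs. With nearly all UMIs in the 10 richest cells, few other cells could hold any. These readings therefore rest on the same observation and are not separate evidence. Of the 8 T-like cells with 10 or more of these UMIs, 7 held none of the 7 CD8 T cell markers, while 1 held all 7 and 1800 of the 2739 UMIs of replicate 1. The share with 3 or more markers has an upper limit of 52.65%, so whether most were joined to T cells or sorted alone stays open. Of Bc1, which is on none of these lists, the 10 richest cells of replicate 1 held 88.46%, as a few cells would give, but 26 of its 52 UMIs lay in cells with 3 or more T cell markers, so other sources stay open for it.

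The cytotoxic effector list was lower in brain mGluR-positive T-like cells. Its median stayed at -0.526 without cells of other-class RNA or few T cell markers, which argues against those cells as the cause. In the main sums it lay at the percentile 0.01 of random lists, so genes of like expression fell less. This argues against a general fall alone. The percentile takes no account of members that vary together or of spread between libraries, so it is no test of the list itself. Without the cluster led by Gm42418 it was -0.5257 (94.3% kept, resampled range 71.2 to 103), so that cluster's part stays open. Another mix of T cell states also stays open. The median was -0.1423 within the largest brain T-like cluster (26 members, 26.3% kept, resampled range -16.3 to 58.3). After reweighting the negative cells, in clusters built without the list's genes, it was -0.2012. As measured by the same ratio it was -0.4315 (46.6% kept, 28.3 to 72.4). Both tests met the rule set beforehand for such a mix. Only the later demand on ranges resampled over the list's genes left it open. A lower level within like T cells is neither shown nor excluded. The call itself is lost with an estimated correlation (adjusted p = 0.807), but that test had almost no power and decides nothing.

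Grm5 UMIs were found in brain mGluR-positive libraries. In T-like cells of replicate 1 there were 1.942 per 100 neuron-marker UMIs (0.707 to 4.275), against 2.42 (1.375 to 3.96) in its empty droplets, as RNA of neurons would give. Transcription by the sorted T cells could not be told apart from none: cells with T cell markers held 1 UMI in 2158641, with an upper limit of 2.581 CPM, and the mGluR-negative library allows up to 0.122. Surface protein was not measured in these files, so low transcript levels do not bear on the staining.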

How the results depend on the processing

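Alternatives on replicates 1 and 3, single cells, the Gm42418 cluster, free RNA and neuron markers were chosen after seeing the data. For brain mGluR-positive against brain mGluR-negative, 57 genes passed. This became 22 with DESeq2's Wald test, 672 with all called cells and 89 with cells holding Cd8a or Cd8b1 and no Cd4 UMI. It became 174 with cells thinned to 1000 UMIs and 0 with the positive libraries counted separately. After thinning 63 genes were higher and 111 lower, against 51 and 6, and 15 were among the 57. The largest brain T-like cluster gave 50 (40 higher, 10 lower), 13 of them among the 57. Other settings gave 40 to 80. Among them, subtracting the largest share of free RNA gave 44 genes higher and 0 lower, so the genes called lower lost their calls. Leaving out replicate 1 or 3, which keeps the other copy of the same sample, gave 54 to 57. Against spleen mGluR-positive, 627 passed. This became 224 with DESeq2's Wald test, 1120 with all called cells, 110 in the largest brain T-like cluster, 160 without a mitochondrial limit and 335 after thinning. Leaving out replicate 1 or 3, which again keeps the other copy, gave 564 to 639. Of the gene lists, 8 and 14 passed in these comparisons (6 to 8, and 14, with replicate 1 or 3 left out). With an estimated correlation or with fry 0 and 0 passed, but these have almost no power with 1 residual degree of freedom. Leaving out replicate 2 was not run, since it leaves 1 distinct library against 1 with no residual degree of freedom. No paired analysis was possible because the groups share only replicate number 1. Of named genes in spleen, 21 differed by 1 or more, 13 with an offset of 5 and 34 with all called cells, and in the mGluR-negative tissues 28 (21 to 29). Grm5 lay above the floor of 3 counts in 2 libraries (brain mGluR-positive replicates 1 and 3, which count as 1 sample), in 4 over all barcodes and in 0 without cells of few T cell markers or other-class RNA. Thinned shares were lower in both positive libraries for 8 genes, 4 without thinning. T-like shares lay below those of the mGluR-negative library in 3 of 3 pairs throughout, but fell from 93.0% to 84.9% in brain mGluR-positive replicate 1 with the stated number of barcodes (6 of 139 cells were then neuron-like, and 4 of 221 in replicate 2), and from 45.6% to 42.2% with doublets kept and 43.2% at resolution 0.5 in spleen mGluR-positive. Spleen mGluR-negative moved from 98.6% to 98.4% with doublets kept. Brain-cell RNA lay above both spleen libraries in 3 of 4 brain libraries (replicates 1 and 3 both counted) for droplets of up to 50 or 10 UMIs, and oligodendrocyte markers in 3 and then 2. In each case the cause was not tested.

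Values that changed sign were these, again with the cause not tested. With all called cells, Fcer1g was at 2.65 against brain mGluR-negative (0.84 with cells holding Cd8a or Cd8b1 and no Cd4 UMI), the naive list at 0.26 there, and the memory CD8 list at 0.21 against spleen. In the largest brain T-like cluster, which held 2 spleen cells, Gzma was at 1.43 against spleen, Tcf7 at 6.358, Slc3a2 at -0.89 and Ifit3 at -0.17. Without cells of few T cell markers or other-class RNA the class II list, with a median of 0.18, changed its tested direction. Within the largest spleen cluster, Ifng was at 0.0300 (0.0511 with doublets kept), Il7r at 0.0128 and Klrg1 at 0.0113. Within the largest cluster of the mGluR-negative tissues, which held 67 brain cells, Ccl1 was at -0.0433, Krt83 at -0.0433 and Isg20 at -0.20. Cx3cr1 was at 0.0124 there, Itgae at -2.655 and Cd8a at -0.21. Among values of named genes under all alternatives, 1408 stayed the same, 72 were weaker, 44 stronger and 14 moved against brain mGluR-negative, and 1377, 132, 24 and 21 against spleen. The 1408 include 87 and 89 from leaving out replicate 1 or 3, where the other copy of the sample stays in. In the comparisons without a test, 170 stayed the same and 146 moved between the spleen sorts, and 202 and 104 between the mGluR-negative tissues. Within the largest T-like cluster, 13 of 40 values stayed the same between the spleen sorts and 2 of 39 between the mGluR-negative tissues. The depth of the T-like sums puts the floor of 3 counts at 3.23 and 2.3 CPM in brain mGluR-positive replicates 1 and 2, with 119 and 181 cells, and at 0.0991 CPM in brain mGluR-negative.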

Other observations

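No hypothesis beyond those weighed above was tested here, and the genes in this part were chosen after their values were seen. Other glutamate receptor genes were read in T-like cells. Gria2 had 22 UMIs in brain mGluR-positive replicate 1 (23.7 CPM, 14.8 to 35.8) and 0 in replicate 2, and none of these lay in cells that kept T cell markers. Grin2b (6 UMIs, 6.45 CPM), Grik4 (5 UMIs, 5.38 CPM) and Gria1 (4 UMIs, 4.3 CPM) were likewise seen in replicate 1. In the spleen mGluR-negative library Grik5 stood at 1.1 CPM (149 UMIs), Gria3 at 0.885 CPM (120 UMIs) and Grm6 at 0.62 CPM (84 UMIs), and in the spleen mGluR-positive library at 0.745, 0.745 and 0.851 CPM. Grik5 stood at 0.628 CPM (19 UMIs) in the brain mGluR-negative library.

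The interferon-induced genes Ifitm1, Ifitm2 and Ifitm3 were higher in spleen mGluR-positive than in spleen mGluR-negative T-like cells (log2 ratios 2.95, 3.41 and 4.32). The interferon response list was lower in that comparison (median -0.32), so a general interferon response is not shown. The Ifitm genes were not called between the brain sorts, although Ifitm1 fell there by 1.46 without cells of few T cell markers or other-class RNA. Their change differed between tissues by edgeR (Benjamini-Hochberg adjusted p = 8.32e-16 for Ifitm3), as did that of Maf, Mt1 and Mt2. Tsix rose in brain mGluR-positive cells by 1.76 (SE 0.33, edgeR adjusted p = 2.54e-05; 78.8 and 99.8 against 23.6 CPM), with empty droplets at 10.4, 5.47 and 11.5 CPM. The mitochondrial gene mt-Nd3 rose by 1.57 (SE 0.38, edgeR adjusted p = 0.00653; 359 and 280 against 95.5 CPM). Its empty-droplet levels were far higher, at 2516 and 3990 against 155 CPM, so free RNA was not told apart from a change in T cells.

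Some genes called higher in brain mGluR-positive cells were concentrated in the empty droplets of replicate 1. Sec61a1 stood there at 48500 CPM, against 99.3 in replicate 2 and 91.4 in the mGluR-negative library, Nfia at 19650 against 31.3 and 9.23, Slx1b at 14360 against 50 and 46.8, and Olfr57 at 7419 against 4.69 and 2.31. In T-like cells Sec61a1 stood at 369 and 54.5 against 44.6 CPM (2.03, SE 0.36), Nfia at 84.2 and 4.61 against 2.97 CPM (3.63, SE 0.44), and Slx1b at 74.4 and 4.61 against 4.36 CPM (2.91, SE 0.43).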
